A study of Homo sapiens with 8 samples.

How the data were processed

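Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in SUDHL6 cells, an established line of diffuse large B cell lymphoma. The 8 samples comprised 3 antibodies (against H3K27me3, EZH2 and H3K36me1) and input DNA, each with DMSO, the solvent control, and with the PRC2 inhibitor iEZH at 1.5 µM for 96 h. Each combination was represented by 1 library, and groups were taken from the antibody and treatment labels. The 6 antibody libraries were analysed as island lists. The 2 inputs were not analysed here.

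Reads were aligned to hg19 with BWA and enriched regions (islands) were found with SICER, per the submitters' processing notes. The tool versions are not given in the sources used here. The names of the deposited lists give a SICER window of 200 bp, a gap of 800 bp and a false discovery rate of 1E-10. They also hold the word uniqnorm, which no source used here explains, so the reads may have been made unique or brought to one depth before they were counted. Each deposited list gives the chromosome, start and end of an island and a count of reads in it, which is a whole number with no scaling stated by the authors. One list was deposited for each library, so islands had been called per library and not on pooled samples. Whether an input library served as the control in calling, and whether the reads had been brought to one depth beforehand, is not given in the sources used here. Total reads per library were not used here, so depth was known only inside islands, where it ranged from 751657 to 13573364 reads. SICER joins neighbouring enriched windows, which suits broad marks but makes island number and width depend on depth.

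Island ends were read as the last base of a window, and coordinates are given 1-based on hg19. For each antibody the DMSO and iEZH lists were compared by the number of islands, the length covered, the reads in islands, and the share of islands with no island of the other treatment overlapping by at least 1 bp. Between antibodies, the share of overlapping islands was set beside the mean and range of 100 random placements of the islands within their chromosomes (seed 20). Placement was uniform along each chromosome, so it did not keep a concentration of islands in one part and did not leave out unsequenced parts. Islands of both treatments were merged into regions, and for regions with islands in both the log2 ratio of iEZH to DMSO reads was taken without scaling. Because a sum over islands called separately moves with the length called, the ratio was also taken per kb of island. No treatment effect was tested, because each group held 1 library. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Reads from PCR without molecular identifiers are not independent molecules, and neighbouring islands are not independent either.

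Regions named in the comparisons were set by a rule chosen before the data were examined. They were the 5 regions with most reads among those with islands in DMSO only, in iEZH only and in both, for each antibody. Regions with islands in both were ranked by DMSO reads, which favours higher DMSO than iEZH values among those named. The densest islands named in the closing section were chosen after their values were seen. Counts at gene promoters and in lists of HOX, developmental, B cell and other genes had been planned, with a provision to leave them out without an hg19 annotation. The gene table used here is of GRCh38.p14, so these results were not run and regions are given by coordinates. Alternatives comprised a common minimum of reads per kb (the lower quartile of islands pooled over both treatments), a minimum width of 2 kb, merging of islands within 5 kb, an overlap of at least 50% of the island, ratios scaled by the reads in islands, regions with at least 50 reads in each library, and leaving out chromosome 6. A value under an alternative was set against the 95% interval of the original one. This was the Clopper-Pearson interval for a share, a binomial interval of the iEZH part of both lengths with islands as the trials for a length, and a sign interval of the median over regions for a ratio. The last 2 kinds treat islands or regions as independent and served only for this purpose.

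Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. The overlap code was tested on simulated lists with known losses, made from the 29188 H3K27me3, 10703 EZH2 and 2135 H3K36me1 islands of the DMSO libraries. It assigned 100% of islands correctly in each, and its overlaps were checked against bedtools 2.31.1.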

Results

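SUDHL6 is a diffuse large B cell lymphoma line with an activating mutation in EZH2, the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3. The series asked how a PRC2 inhibitor, iEZH, changed the distribution of the trimethylated product (H3K27me3), of EZH2 itself and of monomethylated lysine 36 (H3K36me1). Cells had received iEZH at 1.5 µM for 96 h, or DMSO as control. H3K27me3 gave 29188 islands with DMSO and 26376 with iEZH, which held 12628359 and 13573364 reads. EZH2 gave 10703 and 10742 islands with 4738051 and 6249303 reads. H3K36me1 gave 2135 and 1217 islands with 1216620 and 751657 reads. There were no replicates, so differences describe these libraries and have no replicate check, and intervals on shares cover counting error only. Whether reads had been brought to one depth before they were counted is not given in the sources used here.

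The first comparison concerned the H3K27me3 landscape with and without the inhibitor. H3K27me3 islands covered 343 Mb with DMSO and 331 Mb with iEZH, or 96.6% of the DMSO length, and 265 Mb were shared. Covered length was shorter on 17 of 22 autosomes, whereas reads in islands were more on 21 of 22 and reached 107% of DMSO in all. Nearly all wide domains overlapped an island of the other treatment by at least 1 bp. Of islands of at least 50 kb, 1 of 656 with DMSO and 0 of 724 with iEZH had none. A wide island meets such an overlap by chance more often than a narrow one, and the extent shared was not measured by width. The change in length reversed with a common minimum of reads per kb, which gave 102.4%. That minimum was in unscaled reads and weighs against DMSO, whose islands held 36.8 reads per kb against 41.0 with iEZH.

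**Figure D1:**
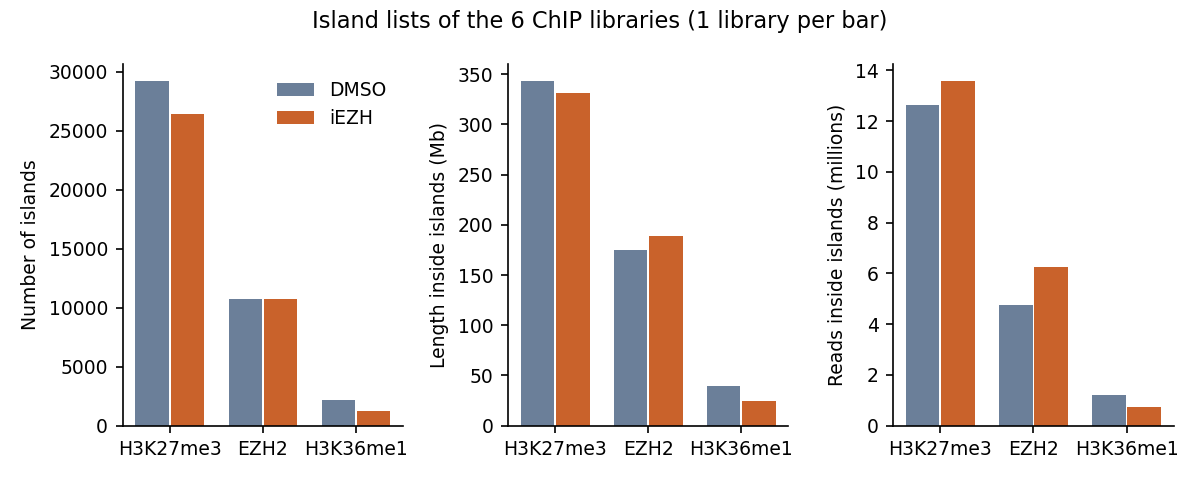
Number of islands, length inside islands (Mb) and reads inside islands for each antibody with DMSO (grey) and iEZH (orange), each bar being 1 library without error. H3K27me3 length was nearly equal (343 and 331 Mb), EZH2 length was greater with iEZH (174 and 189 Mb) and H3K36me1 length was smaller (39.6 and 24.7 Mb).

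H3K27me3 islands found with 1 treatment alone were mainly narrow and weak, in both directions. Of the DMSO islands, 6937 of 29188 (23.8%, 95% interval 23.3 to 24.3%) had no iEZH island over them, and 5505 of 26376 iEZH islands (20.9%, 20.4 to 21.4%) had no DMSO island. With a common minimum of unscaled reads per kb, which weighs against DMSO, the order of these shares turned, to 23.3% and 26.8%. The DMSO islands without a counterpart had a median width of 5.0 kb and 27.5 reads per kb, against 9.0 kb and 31.6 reads per kb for the rest. For iEZH islands these values were 4.6 kb and 27.7 reads per kb against 9.6 kb and 33.7 reads per kb. The share of DMSO islands without a counterpart was 41.9% under 5 kb, 26.3% from 5 to 10 kb, 11.2% from 10 to 20 kb and 3.40% from 20 to 50 kb. Among iEZH islands it was 43.5%, 22.9%, 6.73% and 0.705% in the same classes. Wide islands overlap others by at least 1 bp more readily by chance, so part of this fall may follow from width alone.

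H3K27me3 islands occupied by EZH2 more often had a counterpart, again in both directions. Among H3K27me3 islands with a DMSO EZH2 island, 582 of 10124 (5.75%, 5.30 to 6.22%) had no iEZH counterpart, compared with 6355 of 19064 without EZH2 (33.3%, 32.7 to 34.0%). EZH2-occupied islands were wider, but the share was also lower with EZH2 within each width class. It was 16.8% against 45.2% under 5 kb, 10.5% against 31.0% from 5 to 10 kb, 4.39% against 17.8% from 10 to 20 kb and 1.12% against 14.3% from 20 to 50 kb. At 50 kb or more it was 0 of 641 islands against 1 of 15, a difference that was not detectable with so few islands. Of iEZH H3K27me3 islands, 539 of 10427 with an iEZH EZH2 island (5.17%, 4.75 to 5.61%) and 4966 of 15949 without one (31.1%, 30.4 to 31.9%) had no DMSO counterpart. Read density was not held equal in these comparisons, although islands without a counterpart were also less dense.

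**Figure D2:**
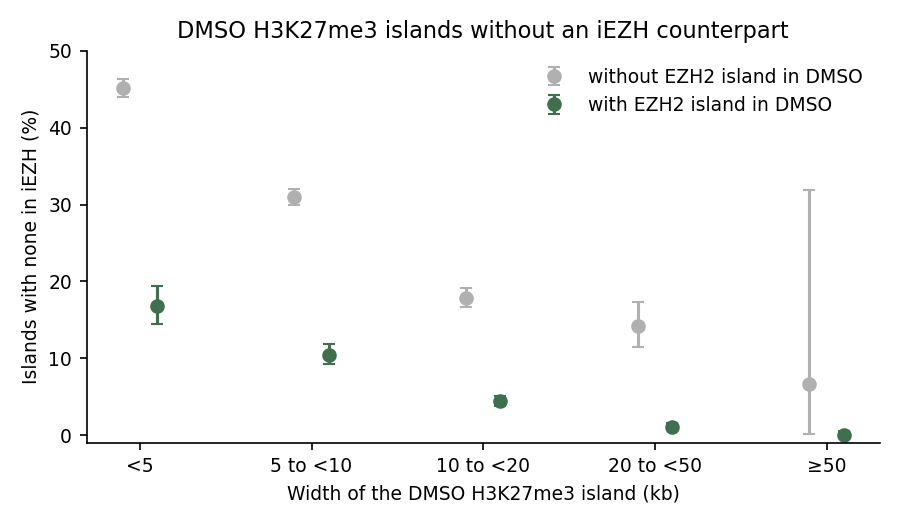
Share of DMSO H3K27me3 islands with no iEZH island (%) by island width (kb), for islands with (green) and without (grey) a DMSO EZH2 island, with Clopper-Pearson 95% intervals. The share fell with width in both classes and was lower with EZH2, from 16.8% against 45.2% under 5 kb to 1.12% against 14.3% from 20 to 50 kb.

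The 5 DMSO-only H3K27me3 regions with most reads all lay on chromosome 6. They were 47616001 to 47678600 (62.6 kb, 1837 reads), 35700001 to 35740000 (1768 reads), 13329201 to 13365800 (1643 reads), 45664001 to 45712000 (1640 reads) and 33385201 to 33413000 (1614 reads). The regions at 35700001 and 33385201 were fully covered by EZH2 islands with DMSO and had no EZH2 island with iEZH. H3K36me1 islands covered 81% and 100% of them with DMSO, and none lay there with iEZH. The region at 13329201 was covered to 100% by H3K36me1 in both treatments. The iEZH-only regions were spread over more chromosomes. The first, on chromosome 9 at 20618601 to 20653200 (1934 reads), was also covered to 97.7% by EZH2 and to 85.0% by H3K36me1 islands that were seen with iEZH only. The others were on chromosome 2 at 38827401 to 38850000 (992 reads), chromosome 8 at 74007001 to 74039600 (925 reads), chromosome 6 at 45381601 to 45394200 (902 reads) and chromosome 22 at 26262801 to 26291800 (849 reads).

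Of the domains present in both treatments, the 5 with most DMSO reads were named. The region on chromosome 11 at 1978001 to 2249000 had 23482 reads with DMSO and 32854 with iEZH, and that on chromosome 6 at 37467401 to 37786600 had 21255 and 24467. Reads were also higher with iEZH on chromosome 6 at 33942001 to 34150800 (18579 and 21531) and on chromosome 10 at 73175601 to 73575200 (17381 and 22967), and lower on chromosome 6 at 43754801 to 43999400 (17882 and 14530). Over 17104 regions with islands in both, the median log2 ratio of reads in islands was 0.15 (quartiles -0.14 and 0.41), a sum that moves with the length called in each library. Per kb of island it was 0.11 (quartiles -0.05 and 0.26), with 37 regions more than 2-fold higher and 4 more than 2-fold lower. Reads were unscaled here, and a region below calling in either library is left out. Rises and falls are therefore not weighed by these 2 counts. Scaling by the reads in islands lowered the median of the sums to 0.044, and library totals were not used here, so an even change of the mark over the genome is not measured by these values.

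The next comparison asked where EZH2 was found with the inhibitor. The number of EZH2 islands was nearly equal, at 10703 with DMSO and 10742 with iEZH, but they covered 174 Mb with DMSO and 189 Mb with iEZH, or 108.5% of the DMSO length. EZH2 islands were longer in sum on 22 of 22 autosomes, from 100.5% to 129.5% of DMSO. For each antibody the autosomes came from the same pair of libraries, so a difference in depth or enrichment would move them together. Reads in EZH2 islands were 132% of DMSO at 27.2 and 33.0 reads per kb, and EZH2 islands of at least 50 kb numbered 422 and 539.

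Of the DMSO EZH2 islands, 2240 of 10703 (20.9%, 20.2 to 21.7%) had no iEZH counterpart, and 3271 of 10742 iEZH islands (30.5%, 29.6 to 31.3%) had no DMSO counterpart. In sum 133 Mb were shared. As with H3K27me3, the share without a counterpart fell with width, from 39.5% of DMSO and 67.9% of iEZH EZH2 islands under 5 kb to 2.61% and 0.742% at 50 kb or more. Here too, part of the fall may follow from width alone. Islands seen with iEZH only were narrower (median 7.6 kb) than those with a DMSO counterpart (15.2 kb). Where an EZH2 island was lost, 1774 of 2240 (79.2%, 77.5 to 80.9%) still overlapped an iEZH H3K27me3 island, against 8405 of 8463 (99.3%, 99.1 to 99.5%) where it was kept. A kept island overlaps an iEZH EZH2 island by definition, and 97.9% of those overlapped iEZH H3K27me3, so the second share was nearly given in advance. Lost islands were also narrower (median 8.2 against 12.8 kb), and width was not held equal.

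Among DMSO-only EZH2 regions, the most reads were on chromosome 6 at 35655001 to 35793600 (138.6 kb, 4591 reads). H3K27me3 covered 75.9% of that region with DMSO and 29.7% with iEZH. The next were chromosome 6 at 36920201 to 37010600 (3173 reads), chromosome 8 at 103722601 to 103831000 (3130 reads), chromosome 2 at 91759401 to 91822000 (2993 reads) and chromosome 6 at 33369401 to 33428200 (2250 reads). The region on chromosome 2 was covered to 97.8% by H3K27me3 in both treatments. Among iEZH-only EZH2 regions, the mitochondrial genome from 1 to 16400 (12621 reads) came first, followed by a 4.2 kb region on chromosome 6 at 58776001 to 58780200 (2915 reads). They held 770 and 694 reads per kb, against 90.4 for the densest DMSO EZH2 island. Neither carried an H3K27me3 island, and whether either was a site of EZH2 was not tested. The others were chromosome 9 at 916201 to 993000 (1879 reads), chromosome 6 at 43455201 to 43491200 (1517 reads) and chromosome 8 at 81770801 to 81811200 (1418 reads), which all carried H3K27me3 in both treatments.

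Of the EZH2 regions found in both treatments, again ranked by DMSO reads, that on chromosome 6 at 43621601 to 44062400 had 19661 reads with DMSO and 16740 with iEZH, at 45.3 and 42.5 reads per kb of island, and that on chromosome 11 at 1797601 to 2077600 had 15015 and 26566, at 56.3 and 94.9 reads per kb. On chromosome 6, reads were 14027 and 16578 at 37433001 to 37778000, 11493 and 9435 at 36571001 to 36827600 (45.3 and 45.1 reads per kb), and 11218 and 14341 at 33942801 to 34132400. The median log2 ratio of reads in islands over 6359 regions was 0.37 (quartiles 0.03 and 0.73). Per kb of island it was 0.22 (quartiles 0.05 and 0.41), with 157 regions more than 2-fold higher and 0 more than 2-fold lower. These densities were unscaled, and regions below calling in either library are not among them. The 2 counts therefore do not weigh rises against falls. Scaling by the reads in islands turned the median of the sums to -0.025.

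EZH2 and H3K27me3 islands coincided in both treatments. With DMSO, 10531 of 10703 EZH2 islands (98.4%, 98.1 to 98.6%) overlapped an H3K27me3 island, and with iEZH 10518 of 10742 (97.9%, 97.6 to 98.2%). Random placement gave 24.0% (range 22.9 to 25.05%) and 22.5% (21.6 to 23.4%). In the other direction, 34.7% of DMSO and 39.5% of iEZH H3K27me3 islands carried EZH2.

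The third comparison concerned H3K36me1, whose island lists differed most between treatments. H3K36me1 islands covered 39.6 Mb with DMSO and 24.7 Mb with iEZH, so that the length fell by 37.7%. Mean density inside called islands was nearly equal at 30.7 and 30.5 reads per kb, which leaves out signal below calling. The length was shorter with iEZH on 21 of 22 autosomes. Few islands had a counterpart in the other treatment, as 1902 of 2135 DMSO islands (89.1%, 87.7 to 90.4%) and 988 of 1217 iEZH islands (81.2%, 78.9 to 83.3%) had none, and 6.43 Mb were shared. Even among H3K36me1 islands of at least 50 kb, 82 of 152 with DMSO (53.9%, 45.7 to 62.1%) had no iEZH island.

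The position of H3K36me1 relative to H3K27me3 differed between the libraries. With DMSO, 322 of 2135 H3K36me1 islands (15.1%, 13.6 to 16.7%) overlapped H3K27me3, below the 21.1% of random placement (range 19.0 to 23.3%). By length, 11.9% lay on H3K27me3, within the random range of 10.8 to 15.2%. Random placement was uniform along each chromosome, whereas 28.0% of the DMSO H3K36me1 length lay in the first 60 Mb of chromosome 6. H3K27me3 and EZH2 islands with DMSO covered 15.6 and 9.34 Mb there, against 4.37 and 1.28 Mb in its rest. A random range that includes chromosome 6 may therefore lie too low, and a depletion is not excluded by it. Without chromosome 6, the share of length on H3K27me3 was 9.62%, below the random range of 10.6 to 15.9%. With iEZH, 755 of 1217 islands (62.0%, 59.2 to 64.8%) overlapped H3K27me3, against 20.01% for random placement (17.3 to 23.7%). Overlap with EZH2 was 10.8% (9.53 to 12.2%) with DMSO and 47.7% (44.9 to 50.6%) with iEZH, where random placement gave 10.1% and 11.1%. By length, DMSO H3K36me1 lay on EZH2 for 11.9%, above the random range of 4.94 to 8.43%, and iEZH H3K36me1 for 46.2%, above 5.05 to 9.21%. Without chromosome 6 these shares were 10.3% (random range 5.11 to 8.02%) and 49.3% (5.17 to 9.54%). With an overlap of at least 50% of the island required, 8.71% of DMSO and 54.6% of iEZH H3K36me1 islands lay on H3K27me3.

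**Figure D3:**
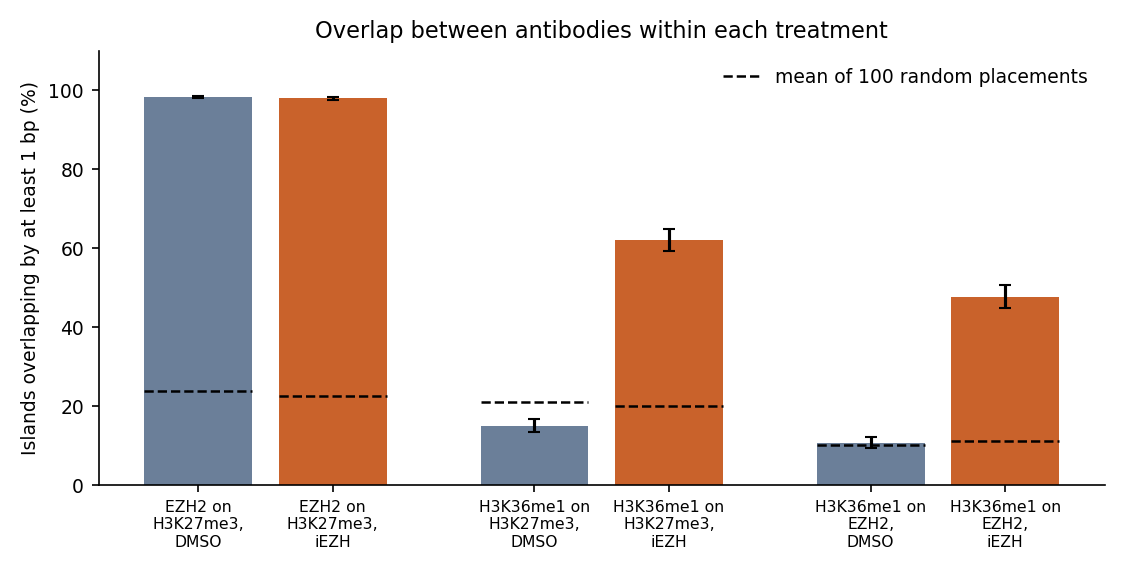
Share of islands (%) that overlapped islands of another antibody in the same treatment by at least 1 bp, with DMSO (grey) and iEZH (orange), Clopper-Pearson 95% intervals (error bars) and the mean of 100 random placements (dashed lines). EZH2 lay on H3K27me3 in both treatments (98.4% and 97.9%), whereas H3K36me1 lay on H3K27me3 for 15.1% of islands with DMSO and 62.0% with iEZH.

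Most of the sequence under iEZH-only H3K36me1 lay in H3K27me3 islands of the DMSO library. Of the 18.2 Mb in H3K36me1 islands with iEZH only, 58.7% lay in H3K27me3 islands of both treatments, 8.88% in those of DMSO only, 4.46% in those of iEZH only and 27.9% in neither. Of the 33.2 Mb with DMSO only, 93.0% lay outside H3K27me3 in both treatments. The shared 6.43 Mb were intermediate, with 60.8% outside.

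The DMSO-only H3K36me1 regions with most reads were chromosome 7 at 92199601 to 92405200 (205.6 kb, 7895 reads), chromosome 6 at 32793601 to 32961600 (7179 reads), chromosome 6 at 52140601 to 52278400 (5017 reads), chromosome 7 at 101572601 to 101694800 (4991 reads) and chromosome 6 at 24990201 to 25140200 (4933 reads). No EZH2 island lay in these, and H3K27me3 was found in the last of them only, over 13.1% of its length with DMSO. The iEZH-only regions lay on chromosome 6 at 37488601 to 37735200 (246.6 kb, 9753 reads), 36201801 to 36331400 (4913 reads), 44419001 to 44551800 (4270 reads) and 372001 to 481200 (4218 reads), and on chromosome 9 at 36731201 to 36838200 (3474 reads). H3K27me3 and EZH2 islands of each treatment covered 78.2% to 100% of each of these 5 regions.

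**Figure D4:**
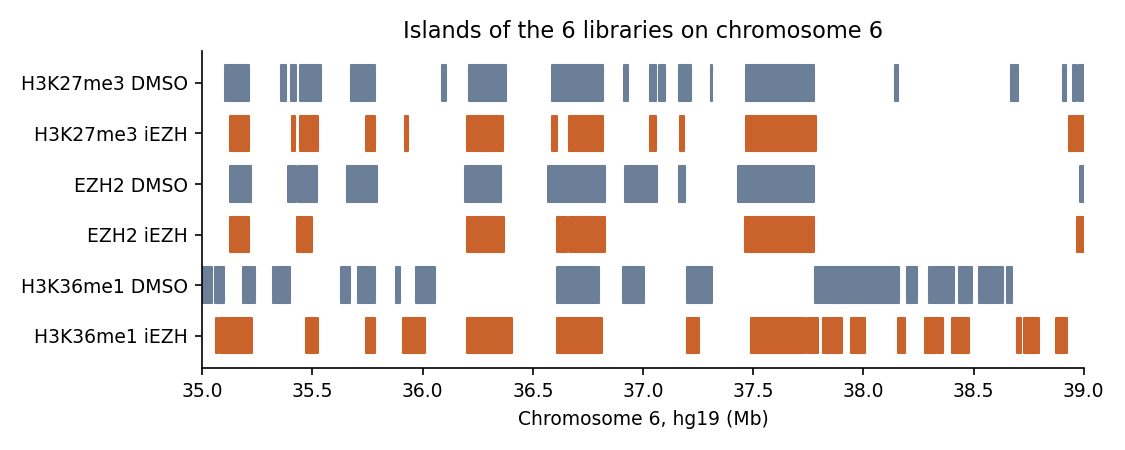
Islands of the 6 libraries between 35 and 39 Mb of chromosome 6 (hg19), with 1 row per library and DMSO in grey and iEZH in orange. H3K36me1 with iEZH filled the domain from 37488601 to 37735200 that held H3K27me3 and EZH2 in both treatments, and H3K36me1 with DMSO lay next to it.

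The H3K36me1 regions found in both treatments with most DMSO reads differed in the length called more than in density. That on chromosome 6 at 43649201 to 44062400, which held H3K27me3 and EZH2, had 15497 reads with DMSO and 17391 with iEZH (41.5 and 43.4 reads per kb of island), and that at 36608801 to 36814200 had 8056 and 8736 (42.5 and 42.9). The 3 of them with little or no H3K27me3 were covered less with iEZH, a direction that ranking by DMSO reads favours. Islands covered 95.4% and 62.2% of chromosome 6 at 37765601 to 38043400, 99.9% and 24.1% of chromosome 6 at 5269601 to 5545600, and 98.1% and 64.3% of chromosome 7 at 69225801 to 69467800. Their densities were 38.6 and 33.7, 34.1 and 30.6, and 33.0 and 28.8 reads per kb of island. Over 197 regions the median log2 ratio of reads in islands was -0.33 (quartiles -0.86 and 0.15), while per kb of island it was -0.043 (quartiles -0.16 and 0.09), and 0 regions differed more than 2-fold per kb. Scaling by the reads in islands turned the median of the sums to 0.36. Density was compared only inside called islands, so signal that fell below calling appears as lost length. Near-equal densities therefore do not show unchanged signal.

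H3K36me1 islands were concentrated on chromosome 6, and less strongly on chromosomes 7 and 8, in both treatments. Chromosome 7 held 15.3% of the H3K36me1 length with DMSO and 13.1% with iEZH, against 6.21% and 6.01% for H3K27me3. Chromosome 8 held 9.44% and 7.02%, against 3.51% and 3.67% for H3K27me3. The first 60 Mb of chromosome 6 held 28.0% of the H3K36me1 length with DMSO and 36.2% with iEZH, against 4.54% and 4.12% of the H3K27me3 length and 5.35% and 4.71% of the EZH2 length. Islands of each antibody were wider there, with DMSO medians of 48.3 kb against 10.6 kb elsewhere for H3K36me1, 34.6 against 11.6 kb for EZH2 and 19.8 against 7.6 kb for H3K27me3. Outside chromosome 6, the share of H3K36me1 islands on H3K27me3 was 14.0% (12.5 to 15.7%) with DMSO and 63.5% (60.4 to 66.4%) with iEZH.

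**Figure D5:**
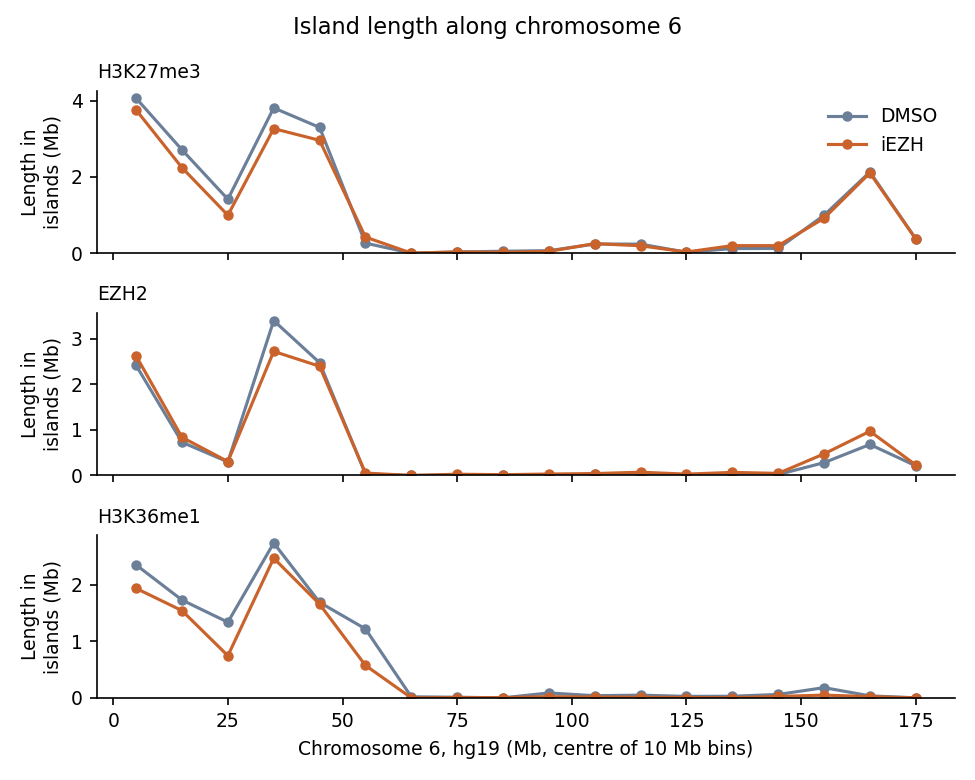
Length inside islands (Mb) in 10 Mb bins along chromosome 6 (hg19, bin centres in Mb) for H3K27me3, EZH2 and H3K36me1, with DMSO in grey and iEZH in orange, 1 library per line. The first 60 Mb held most of the island length of the chromosome for each antibody, and 28.0% and 36.2% of the whole H3K36me1 length with DMSO and iEZH.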

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

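The tests of stray H3K27me3 reads, of chromosome 6, of DNA copies and of depth were chosen only after the result was seen, and that of the strongest islands was chosen before. Antibodies moved in opposite directions between treatments, and these differences were not tested, since each group held 1 library. The covered length changed by -37.7% for H3K36me1 and by 8.49% for EZH2. The share of islands on H3K27me3 changed by 47.0 percentage points for H3K36me1 and by -0.478 percentage points for EZH2, and the 95% intervals of the EZH2 shares overlapped.

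H3K36me1 islands lay mostly on H3K27me3 in the iEZH library (62.0%) and seldom in the DMSO library (15.1%). Stray reads of the iEZH H3K27me3 library would raise every H3K27me3 island in proportion, but of the H3K27me3 islands at least as wide and as dense as one with H3K36me1, a median of 14.5% had H3K36me1 too (5th and 95th percentiles 5.66 and 23.8%), which argues against such reads alone. Of the 858 H3K27me3 islands with H3K36me1, 12.8% were among as many densest ones and 19.2% among those with most reads, above the 3.25% of chance, so a part played by such reads stays open. Chromosome 6 did not account for the pattern, as 63.5% of iEZH islands off chromosome 6 overlapped H3K27me3, nor did a smaller set of stronger islands, as 20.1% of the 1217 DMSO islands with most reads did so. The iEZH H3K36me1 library held 36.2% of its length in the first 60 Mb of chromosome 6. This was near the 28.0% of DMSO H3K36me1 and far from the 4.12 to 5.35% of H3K27me3 and EZH2. Its 1217 islands were, however, far fewer than theirs, and a short list of strong regions could concentrate there too. Of the 5 named regions found in both treatments, 3 for H3K27me3 and 4 for EZH2 lay on chromosome 6. An exchange with an H3K27me3 or EZH2 library is therefore not decided by this share. Reads of libraries other than iEZH H3K27me3, exchanged treatment labels and a difference between immunoprecipitations or inputs were not tested. As a hypothesis, an effect of the inhibitor was not tested either, and each of these may play a part.

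H3K36me1 islands were concentrated in the first 60 Mb of chromosome 6. Chromosomes 7 and 8 also held a larger part of the H3K36me1 length than of the H3K27me3 or EZH2 length, and were not examined further. A candidate explanation is extra DNA copies of this part in the cells, which would raise read numbers for every antibody. Median reads per kb of island were higher there than elsewhere in all 6 libraries, at 39.4 against 30.4 for DMSO H3K27me3, 30.3 against 23.8 for DMSO EZH2 and 34.6 against 26.25 for DMSO H3K36me1, which goes with extra copies but also with the wider islands there. Island length exceeded that in the rest of the chromosome, with ratios of 3.14 to 7.29 for H3K27me3 and EZH2 and of 20.9 and 57.1 for H3K36me1. Copies that raised all antibodies equally would not give the greater H3K36me1 excess unless weak H3K36me1 signal passed the calling threshold mainly there. The input libraries were not used here, so extra copies and a richer set of marked sites cannot be told apart, and no biological explanation was tested.

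The length in H3K27me3 islands was nearly the same with the inhibitor of the enzyme that makes the mark. Libraries brought to one depth before islands were found could hide an even fall of the mark, because the remaining signal is then scaled up. Reads in H3K27me3 islands were 107.5% of DMSO. An unchanged mark could give a value near this. An even fall after scaling could do so too if few reads were background outside islands, whose number was not known. An even fall and an unchanged mark cannot be told apart without library totals or an outside standard. Whether the inhibitor lowered the mark in these cells was therefore not tested.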

How the results depend on the processing

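All alternatives were planned except those without chromosome 6, which were chosen after seeing the data. Of 64 alternatives, 33 left the value within the interval set for this comparison, 29 moved it and 2, both by scaling, changed its sign. Except for scaling, the cause was not tested. A common minimum of 26.9, 21.7 and 23.7 unscaled reads per kb was set for H3K27me3, EZH2 and H3K36me1. It weighs against the library of lower density, which was DMSO for H3K27me3 and EZH2. The iEZH length was then 102.4% of DMSO for H3K27me3, on the other side of equality from 96.6%, and 122% for EZH2. Islands without a counterpart were then 23.3% of DMSO and 26.8% of iEZH H3K27me3, the reverse of their order at 23.8% and 20.9%, 18.1% of DMSO and 38.3% of iEZH EZH2, and 87.0% of DMSO and 78.1% of iEZH H3K36me1. H3K27me3 lay under 97.4% of DMSO and 96.7% of iEZH EZH2 islands and 16.9% of DMSO H3K36me1 islands. A minimum width of 2 kb left 20.3% of iEZH H3K27me3 islands without a counterpart. Merging within 5 kb gave 28.5% of DMSO and 23.6% of iEZH H3K27me3 islands and 24.0% and 32.6% of EZH2 islands. An overlap of at least 50% gave 29.1% and 27.1% for H3K27me3, 25.9% and 38.6% for EZH2 and 92.6% and 84.6% for H3K36me1. H3K27me3 then lay under 96.0% of DMSO and 95.6% of iEZH EZH2 islands and 8.71% of DMSO and 54.6% of iEZH H3K36me1 islands. Without chromosome 6, H3K36me1 length was 55.6% of DMSO, and 91.8% of DMSO and 85.6% of iEZH islands had no counterpart. Ratios scaled by the reads in islands had a median log2 of 0.044 for H3K27me3, and changed sign to -0.025 for EZH2 and 0.36 for H3K36me1. This scaling shifts all regions of an antibody by 1 constant, so these changes follow from the library sums alone and say nothing of single regions. Promoter alternatives were not run for want of an hg19 annotation. Depth outside islands was not known, which limits all comparisons of amount.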

Other observations

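The comparison of losses at H3K36me1 sites and the densest islands named here were chosen after the data were seen. H3K27me3 islands that overlapped a DMSO H3K36me1 island were lost with iEZH more often than others, at 134 of 359 (37.3%, 95% interval 32.3 to 42.6%) against 6803 of 28829 (23.6%, 23.1 to 24.1%). The gap was wider among islands of similar width, at 40.2% against 10.8% from 10 to 20 kb and 26.5% against 2.56% from 20 to 50 kb. Outside chromosome 6 the values from 20 to 50 kb were 15.9% (8.72 to 25.6%) and 2.16% (1.67 to 2.74%). EZH2 islands on DMSO H3K36me1 were also lost more often, at 73 of 236 (30.9%, 25.1 to 37.3%) against 2167 of 10467 (20.7%, 19.9 to 21.5%). H3K27me3 islands from 10 to 20 kb with H3K36me1 in iEZH and none in DMSO were lost at 7.96% (4.62 to 12.6%). The reverse split showed no such excess, as iEZH H3K27me3 islands from 10 to 20 kb had no DMSO counterpart for 4.64% (2.34 to 8.15%) with an iEZH H3K36me1 island and 6.81% (6.20 to 7.46%) without one.

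The mitochondrial genome carried an island in the iEZH EZH2 library alone, with 12621 reads at 770 reads per kb. The next densest island of that library was on chromosome 6 at 58776001 to 58780200 with 694 reads per kb, and the third was on chromosome 1 at 121483201 to 121485600 with 308 reads per kb. The densest DMSO EZH2 island, on chromosome 1 at 2620801 to 2623200, had 90.4 reads per kb. Whether the very dense iEZH islands were sites of EZH2 was not tested.

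Among the densest H3K36me1 islands, a stretch of chromosome 1 recurred with both treatments. The island from 144986001 had 3582 reads with DMSO and 4188 with iEZH, at 57.4 and 66.1 reads per kb. Regions of repeated sequence were not filtered out here, and whether this stretch was a site of the mark was not tested.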
